A study of Mus musculus with 6 samples.

How the data were processed

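RNA was measured in the neocortex of 6 mice at postnatal day 0, the day of birth. Per the labels, 3 animals were wild type (WT) and 3 were conditional knockouts (cKO) with floxed Tcf4 alleles and a Cre recombinase driven by Emx1, a gene active in the progenitors of cortical excitatory neurons and glia. The strain was C57BL/6, RNA was extracted with Trizol, and libraries were made with a TruSeq RNA kit. The labels do not say whether the kit marked strand. Group and replicate number were taken from the sample titles, which carry 6 different animal codes, so the replicates of a group were treated as different animals. The libraries are called WT 1, WT 2, WT 3, cKO 1, cKO 2 and cKO 3.

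The deposited table held FPKM values (fragments per kilobase of exon, scaled to library size), computed by the authors and named as such per the file headers. Per the submitters' processing notes, base calls were converted with bcl2fastq 1.8.4, reads were aligned to mm10 with STAR 2.5.4b and assigned to genes with featureCounts 1.6.1, and R 3.4.1 and DESeq2 1.22.1 were used. The annotation release, the strand setting of the counting and the filter on low genes are not given in the sources used here. The table listed 15703 genes, followed by 139 blank lines that were left out. By gene identifier, 15661 genes matched the GENCODE M21 annotation of the mouse genome build mm10, which supplied coordinates, exon lengths and GC content, and 42 did not match. The lowest mean over the 6 libraries was 0.466 CPM (counts per 1e6 reads), 3 genes lay under 0.5 CPM and the first percentile was 0.750 CPM, so low genes had been removed before deposit and no further filter was applied.

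Depth was recovered from the table. Each FPKM value was multiplied by the gene's exon length and by a library size chosen so that values of low genes came out as whole reads. Over 1316 to 1522 genes per library with at most 50 reads and an exon length under 3000 bases, 94.7% to 95.4% of values lay within 0.1 of a whole read, against 19.0% to 22.0% at a wrong library size. The library sizes so chosen were 23.2 to 26.0 M (1e6 reads). The summed reads in listed genes were 25.4 to 28.7 M per library. In each library they exceeded the chosen size, so they are approximate and may be too high. Because exon lengths came from an annotation that may differ from the authors', these reads were used for depth, shares of reads and 1 alternative fit only.

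The design written before the data were examined assumed read counts and named a count model. For a table of normalised values it named limma on log2(value + 1), or a count test where whole reads could be recovered. Since the table held FPKM, limma 3.58.1 in R 4.3.3 was used, with a mean-variance trend and robust empirical Bayes moderation, on log2(FPKM + 1), with genotype as the only term. P-values were adjusted over the 15703 genes by the Benjamini-Hochberg method, and a gene was called higher or lower in cKO at an adjusted p under 0.05. Adjusted p-values given for genes are from this test, n = 3 per group, unless another is named. Log2 fold changes on the log2(FPKM + 1) scale understate the change of low genes, so ratios of mean FPKM are given as fold changes. Summary tables and the other tests were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

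Gene lists for cortical cell types, layers, adhesion and guidance families, signalling pathways, channels, synapses, metabolism and stress were fixed before the data were examined, and 46 of them with at least 4 measured members were tested. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, 2-sided, with Benjamini-Hochberg adjustment over the 46 lists. Camera with a correlation estimated for each list and limma's fry were alternatives. For each list, the number of called members is given over all genes and adjusted over the list alone. A sex-linked list served to check the libraries.

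The genes named were chosen by a rule fixed before the data were examined. It took Tcf4 and its paralogs Tcf3 and Tcf12. It took the 12 largest increases and the 12 largest decreases on the log2(FPKM + 1) scale among called genes with a mean of at least 1 CPM, an official symbol, no sex linkage and groups that did not overlap. From each list it took up to 4 called members with the smallest p, or up to 2 members, as values only, where none was called. Further members are named where a list held 5 or fewer called members in a direction. These, together with Cux2, Bcl11b, Fezf2 and Tbr1 and the genes named only in the closing observations, were chosen after their values were seen. Some genes that the rule takes are not reported here.

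The fit was tested on simulated data built from the 15703 genes and the spread of the real libraries. Of 50 genes changed at each size, 14% were recovered at 1.25-fold, 70% at 1.5-fold, 88% at 2-fold and 96% at 4-fold, and 4.96% of the calls were unchanged genes. With no change simulated, 2 genes were called. Only 200 genes in all were changed, against 2483 called in the real data. The adjustment is stricter where fewer genes change, so the recovered shares may be too low for the real data. The list test called the 1 list shifted by 0.3 log2 and no other. The simulated genes varied independently, while the estimated correlation within real lists reached 0.927 (ribosomal proteins). The simulation therefore does not show how the list test behaves where members are correlated.

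Alternatives fixed beforehand were pseudocounts of 0.1 and 5, limma voom on the recovered reads, a mean of at least 1 CPM, an adjusted p under 0.01, the replicate number as a block, sex as a covariate, camera with an estimated correlation, fry, and each library left out in turn. Chosen after the data had been seen were median-of-ratios and upper-quartile scaling of the FPKM, a mean FPKM of at least 1, a correction of each library for exon length and GC content by splines, that correction with the replicate block, limma's treat for a change of more than 1.2-fold in place of the planned count-based test of that size, and leaving out both libraries at the ends of the length trend (WT 3 and cKO 1). The planned count models and surrogate variables were not run, because the table holds FPKM and whole reads were checked for low, short genes only.

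Reads of genes that overlap on opposite strands cannot be told apart unless the counting used strand, and near-identical copies can share reads. Exon overlaps of named genes were taken from the annotation and are named beside the values where they cover at least 15% of a gene's exon length.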

Results

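Gene expression was measured by RNA sequencing of whole neocortex from newborn mice, 3 WT and 3 Tcf4 cKO. Reads in listed genes were recovered from the FPKM values and are approximate. They numbered 28.7, 26.5 and 25.4 M (1e6 reads) in WT 1, 2 and 3 and 25.8, 26.7 and 25.5 M in cKO 1, 2 and 3. The study was designed to ask how expression changes once the transcription factor Tcf4 is lost, and its title concerns adhesion and the positioning of projection neurons. Values are mean FPKM ± SD of the 3 libraries of a group, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 15703 genes unless stated otherwise.

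Tcf4 (ENSMUSG00000053477, chromosome 18, 69343356 to 69689079, plus strand, mm10), the targeted gene and a basic helix-loop-helix transcription factor of the E-protein class, was lower in every cKO library. Its expression was 71.2, 75.6 and 75.3 FPKM in WT and 56.5, 60.6 and 55.3 FPKM in cKO. The mean fell from 74.1 ± 2.45 to 57.4 ± 2.76 FPKM, a log2 change of −0.36 (SE 0.0617, limma adjusted p = 0.00411). The value counts all annotated exons and all cells of the tissue, so it does not isolate the floxed exon or the Emx1 lineage. Of the paralogous E-protein genes, Tcf3 (chromosome 10, 80409514 to 80433647, minus strand) rose from 15.9 ± 0.580 to 18.8 ± 0.978 FPKM (limma adjusted p = 0.0465). This call was lost without 5 of the 6 libraries, with an adjusted p of up to 0.184 without cKO 2. Tcf12 (chromosome 9, 71842688 to 72111871, minus strand) was at 6.76 ± 0.564 FPKM in WT and 7.97 ± 0.429 FPKM in cKO and did not pass (limma adjusted p = 0.0986).

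In the cKO neocortex, the largest decreases included the neuropeptide gene Nts (96.0-fold lower), the helix-loop-helix inhibitor Id2 and the axonal adhesion molecule Cntn2. The transcription factor Neurod1 and the glycine receptor subunit Glra2 rose. Of the markers of upper cortical layers and of astrocytes, 12 of 22 and 13 of 19 fell, and 9 of 28 interneuron and 7 of 18 microglia markers fell. Without WT 1, 3 interneuron and 2 microglia markers were called lower. Among adhesion genes, Cntn2, Mdga1 and Fn1 fell and Kirrel and Itgb8 rose, while no clustered protocadherin passed. Among 15703 genes, limma called 1134 higher and 1349 lower in cKO. Protein-coding genes made up 946 and 997 of these, and processed pseudogenes 7 and 220.

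Nts (ENSMUSG00000019890, chromosome 10, 102481756 to 102490486, minus strand), which encodes neurotensin, fell from 135 ± 6.74 to 1.40 ± 0.505 FPKM, a 96.0-fold lower level (limma adjusted p = 7.28e-09). Its level was 131, 130 and 143 FPKM in WT and 0.970, 1.96 and 1.28 FPKM in cKO. Id2 (ENSMUSG00000020644, chromosome 12, 25093799 to 25097140, minus strand), which encodes an inhibitor of basic helix-loop-helix factors, fell from 313 ± 61.6 to 35.9 ± 5.12 FPKM (8.71-fold lower, limma adjusted p = 2.93e-06). Cntn2 (ENSMUSG00000053024, chromosome 1, 132509427 to 132543256, minus strand), an immunoglobulin-superfamily adhesion molecule of axons, fell from 101 ± 1.55 to 16.9 ± 0.737 FPKM (5.97-fold lower, limma adjusted p = 9.54e-09). The neurofilament genes Nefl (30.8 ± 0.473 to 4.18 ± 0.641 FPKM) and Nefm (30.5 ± 2.65 to 7.11 ± 0.649 FPKM) fell together, although their exons share 1108 bases on opposite strands and part of their reads cannot be separated without strand. Lipoprotein lipase, Lpl, fell from 9.82 ± 0.685 to 0.779 ± 0.176 FPKM, and the activin-binding Fst from 7.07 ± 0.941 to 0.404 ± 0.0659 FPKM. The remaining genes among the 12 largest decreases on the log2(FPKM + 1) scale were Dkk3, Vgf, Gdf10, Cbln4 and Ntf3, which fell 4.66-fold (Ntf3, neurotrophin 3) to 11.2-fold (Cbln4, a secreted synaptic organiser).

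Neurod1 (ENSMUSG00000034701, chromosome 2, 79452521 to 79456751, minus strand), a basic helix-loop-helix factor of neuronal differentiation, rose from 7.82 ± 0.744 to 32.0 ± 2.5 FPKM, a 4.09-fold higher level (limma adjusted p = 9.26e-07). Its level was 7.08, 8.57 and 7.82 FPKM in WT and 31.1, 34.8 and 30.1 FPKM in cKO, and 7.4% of its exon length is shared with Cerkl. Glra2 rose from 25.1 ± 1.01 to 63.0 ± 1.8 FPKM (2.51-fold, limma adjusted p = 1.64e-06). The melanocortin receptor Mc4r rose from 2.75 ± 0.938 to 10.2 ± 0.886 FPKM and the potassium channel gene Kcnh4 from 2.24 ± 0.830 to 7.41 ± 1.53 FPKM. Adgrg6, an adhesion G protein-coupled receptor, rose 12.2-fold from a low level of 0.193 ± 0.0404 to 2.35 ± 0.232 FPKM. The mTOR inhibitor Deptor rose 8.63-fold, from 0.267 ± 0.0192 to 2.31 ± 0.209 FPKM. The other genes among the 12 largest increases on that scale were Arhgap28, Ndst3, Tmem200c, Cplx3, Fam135b and Cxxc4, with rises of 2.51-fold (Cxxc4) to 4.45-fold (Cplx3).

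**Figure D1:**
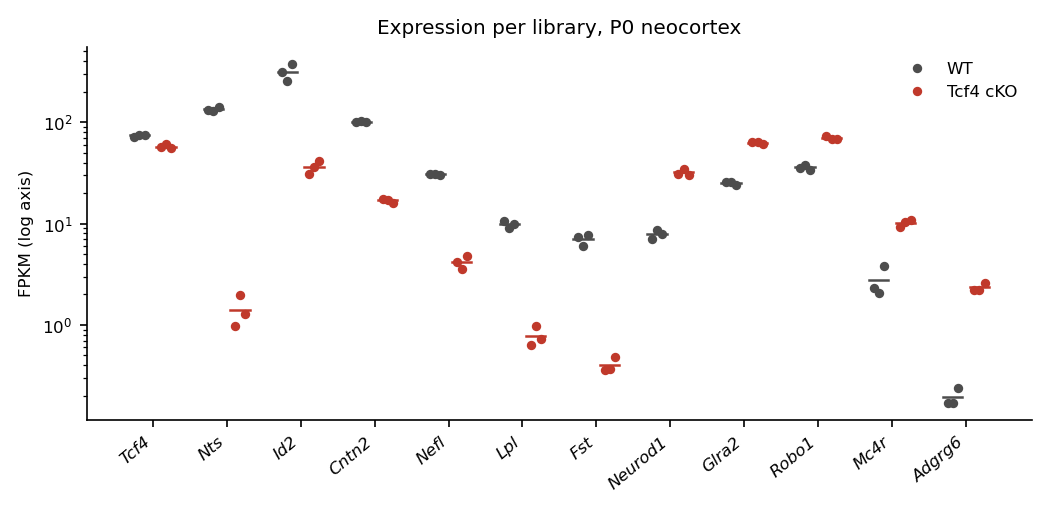
Expression in FPKM (log axis) of Tcf4 and 11 other genes in each library, with WT in grey, Tcf4 cKO in red and a line at each group mean. Nts lay at 130 to 143 FPKM in the 3 WT libraries and at 0.970 to 1.96 FPKM in the 3 cKO libraries, and Neurod1 at 7.08 to 8.57 and 30.1 to 34.8 FPKM.

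Most called changes were small. The median absolute log2 change of the 2483 called genes (15.8% of those tested) was 0.41, with 31 called genes higher and 77 lower by at least 1 log2 unit, and the median of all genes was 0.0017. Without WT 1, cKO 1 or cKO 2, 544, 566 and 578 genes were called higher and 830, 830 and 839 lower, and 1082 of the 2483 calls held without each library in turn (421 higher, 661 lower). The groups did not overlap in 5854 genes (37.3%), against 10% by chance. Across genes, which are not independent replicates, the log2 change rose with exon length (Spearman rho 0.231 over 15655 genes). Genes called higher had a median exon length of 5093 bases, those called lower 3118 and the others 4261.

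**Figure D2:**
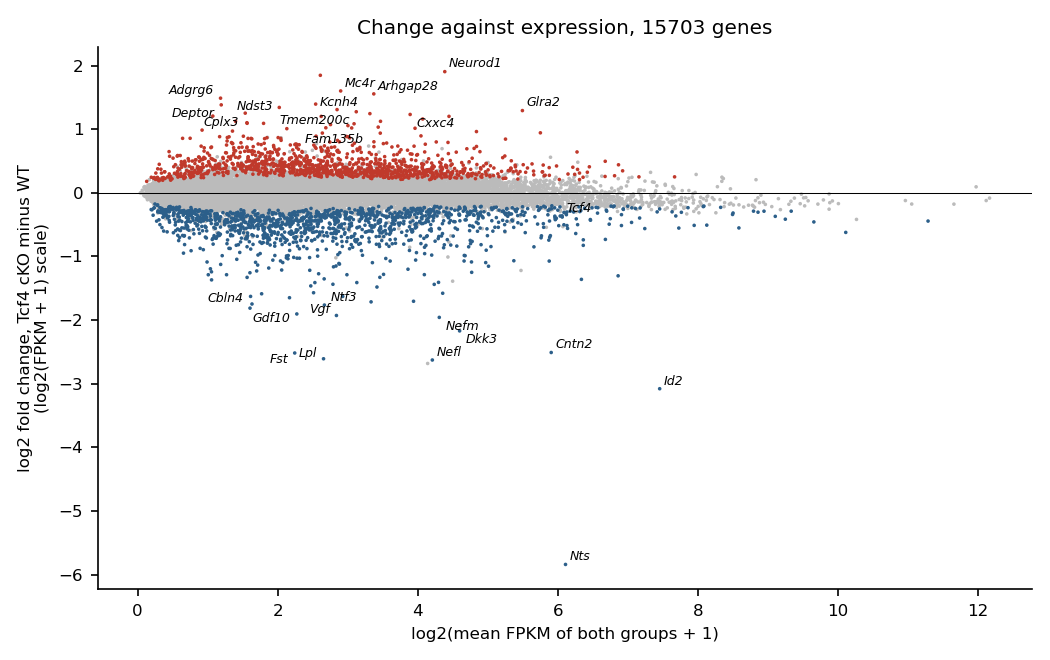
Log2 fold change (Tcf4 cKO minus WT, on the log2(FPKM + 1) scale) against the log2 of the mean FPKM of both groups + 1, for 15703 genes. The 1134 genes called higher are red, the 1349 called lower are blue and the rest grey, and Nts stands lowest at −5.84.

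Of 18 measured helix-loop-helix partners and related factors, 3 rose (Neurod1, Neurog2, Tcf3), 4 fell (Id2, Id3, Olig1, Neurod2) and 11 did not pass. Adjusted over the list alone, 6 were higher and 4 lower, and the list had no shift in 1 direction (camera adjusted p = 0.812). Id3, a further inhibitor of these factors, fell from 10.9 ± 0.991 to 5.37 ± 0.551 FPKM (limma adjusted p = 0.000178), and Olig1, a factor of the oligodendrocyte lineage, from 33.8 ± 1.35 to 22 ± 2.31 FPKM (limma adjusted p = 0.000981). The calls of Tcf3 and Neurod2 were each lost without 5 libraries, with an adjusted p of up to 0.184 for Tcf3 (without cKO 2) and 0.134 for Neurod2 (without cKO 3).

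Among 22 markers of upper-layer projection neurons, 12 fell, 1 rose (Pou3f2) and 9 did not pass, with the same counts adjusted over the list alone. Lpl and Dkk3 fell most, Dkk3 from 38.6 ± 4.39 to 7.80 ± 0.706 FPKM. The semaphorin receptor Plxnd1 fell from 12.9 ± 0.597 to 5.51 ± 0.238 FPKM (limma adjusted p = 9.72e-06) and the adhesion molecule Mdga1 from 19.2 ± 1.19 to 7.82 ± 0.718 FPKM (limma adjusted p = 1.35e-05). Pou3f2, a transcription factor of upper-layer neurons, rose from 40 ± 3.12 to 52.8 ± 3.19 FPKM. The list was lower in cKO, with a median log2 change of −0.44 (camera adjusted p = 2.5e-07; adjusted p = 0.15 with an estimated correlation).

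Cux2, Bcl11b, Fezf2 and Tbr1, transcription factors of projection neuron classes, did not pass limma's test. Cux2 was at 21.6 ± 1.29 FPKM in WT and 20.3 ± 1.77 FPKM in cKO, Bcl11b at 33.8 ± 4.88 and 34.0 ± 1.69 FPKM, Fezf2 at 34.5 ± 3.19 and 38.4 ± 4.19 FPKM, and Tbr1 at 43.6 ± 1.14 and 39.5 ± 1.36 FPKM. These 4 genes were chosen after their values were seen.

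Of 24 markers of layers 5 and 6, 9 fell, 3 rose (Crim1, Otx1, Etv1) and 12 did not pass, and adjusted over the list alone 12 were lower and 4 higher. Among markers of layer 6 neurons, Rprm fell from 78.7 ± 2.58 to 36.9 ± 1.76 FPKM (limma adjusted p = 5.85e-06), Syt6 from 8.62 ± 1.04 to 3.89 ± 0.221 FPKM and the neurotensin receptor Ntsr1 from 19.8 ± 2.71 to 9.79 ± 0.458 FPKM. The transcription factor Sox5 fell from 14.7 ± 0.379 to 10.3 ± 0.513 FPKM. The list was lower (camera adjusted p = 0.0196; adjusted p = 0.774 with an estimated correlation), and this call was lost without WT 2 (adjusted p = 0.0724). Otx1 and Etv1 lost their calls without 4 and 5 libraries, with adjusted p of up to 0.129 (without WT 1) and 0.157 (without cKO 2). Without WT 1, WT 3, cKO 2 or cKO 3, 1 member of the list was called higher.

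Subplate markers went the other way. Of 17 measured, 7 rose, 3 fell (Nr4a2, Hs3st4, Nrgn) and 7 did not pass, with the same counts adjusted over the list alone. Cplx3, a complexin of subplate neurons, rose from 0.698 ± 0.0593 to 3.10 ± 0.907 FPKM (limma adjusted p = 0.000328). Kcnab1 rose from 2.52 ± 0.122 to 4.96 ± 0.342 FPKM, the matricellular gene Ccn2 from 3.26 ± 0.319 to 7.19 ± 1.1 FPKM and Pappa2 from 1.93 ± 0.270 to 4.31 ± 0.482 FPKM. A non-coding gene on the opposite strand shares 23.2% of the exon length of Ccn2. The list was higher (camera adjusted p = 0.0407, and 0.808 with an estimated correlation). It lost its call without WT 2 (camera adjusted p = 0.0566), without cKO 3 (0.0788), with the length and GC correction (0.0715) and with the replicate number as a block (0.0702). Nrgn lost its call without 3 libraries, with an adjusted p of up to 0.135 without WT 1. Of 11 Cajal-Retzius cell markers, 1 fell (Calb2, 8.05 ± 0.771 to 5.45 ± 0.354 FPKM), 1 rose (Cacna2d2, a call lost without 4 libraries, adjusted p of up to 0.0970 without cKO 1) and 9 did not pass (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.614).

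Markers of basal progenitors and of dividing cells included genes that rose. Eomes, the marker transcription factor of intermediate progenitors, rose from 6.78 ± 0.332 to 12 ± 2.02 FPKM (limma adjusted p = 0.00165) and Neurog2 from 5.23 ± 0.629 to 9.54 ± 1.90 FPKM (limma adjusted p = 0.00359). Of 15 intermediate progenitor markers, 4 rose (Eomes, Neurog2, Mfng, Mfap4), 1 fell (the somatostatin receptor Sstr2, 14.8 ± 3.28 to 5.21 ± 0.648 FPKM) and 10 did not pass, and 5 were higher and 1 lower adjusted over the list alone. The list did not pass (camera adjusted p = 0.378), but was higher without cKO 1 (adjusted p = 0.0415) and without both WT 3 and cKO 1 (0.0409). Mfap4 lost its call without 4 libraries, with an adjusted p of up to 0.138 without cKO 2.

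Of 34 cell cycle and replication genes, 8 rose, none fell and 26 did not pass, and 10 were higher adjusted over the list alone. The spindle gene Tpx2 rose from 4.57 ± 0.430 to 6.06 ± 0.203 FPKM, the mitotic motor Kif11 from 3.4 ± 0.206 to 4.66 ± 0.559 FPKM, Bub1b from 3.60 ± 0.512 to 4.85 ± 0.312 FPKM and Cdc20 from 4.32 ± 0.231 to 5.62 ± 0.603 FPKM, with limma adjusted p of 0.0184 to 0.0385. The list was higher, with a median log2 change of 0.24 (camera adjusted p = 0.000184; adjusted p = 0.808 with an estimated correlation). The number of called members depended on the libraries, with 0 without WT 1, cKO 2 or cKO 3, 2 without WT 3 and 13 without cKO 1. The 4 named genes lost their calls without 3 to 5 libraries, with adjusted p of up to 0.15 (Cdc20 without cKO 2).

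Of 23 radial glia markers, 6 fell, 2 rose (Prom1, Emx2) and 15 did not pass, with the same counts adjusted over the list alone. Fabp7, a fatty acid binding protein of radial glia, fell from 454 ± 4.25 to 312 ± 47.5 FPKM (limma adjusted p = 0.00562), Sox9 from 10.1 ± 0.5 to 7.40 ± 0.914 FPKM and Aldoc from 31.8 ± 4.41 to 21.7 ± 3.49 FPKM, while Prom1 rose from 2.93 ± 0.167 to 4.45 ± 0.0486 FPKM. The list did not pass (camera adjusted p = 0.214), but was lower without WT 3 (0.0248) and without cKO 2 (0.0310). Without WT 1 and cKO 1, 1 and 2 members were called lower. Sox9 lost its call without WT 1 (adjusted p = 0.0581), Aldoc without 2 libraries (up to 0.0676 without WT 1) and Emx2 without 4 (up to 0.136 without cKO 2).

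Most astrocyte markers fell. Of 19 measured, 13 fell, none rose and 6 did not pass, and 16 were lower adjusted over the list alone. Apoe, the main lipoprotein of astrocytes, fell from 41.4 ± 6.44 to 22.6 ± 3.66 FPKM (limma adjusted p = 0.00179), the bicarbonate transporter Slc4a4 from 3.93 ± 0.663 to 1.84 ± 0.126 FPKM and the metallothionein Mt1 from 12.5 ± 1.42 to 6.77 ± 1.37 FPKM. The median log2 change was −0.53 (camera adjusted p = 3.38e-08; adjusted p = 0.725 with an estimated correlation). Of 17 oligodendrocyte lineage markers, 3 fell (Olig1, Cspg5, Pdgfra), 1 rose (Mog, 13.4 ± 1.82 to 18.6 ± 0.980 FPKM) and 13 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.126). That list was lower without cKO 3 (adjusted p = 0.0498), and Pdgfra lost its call without 2 libraries (up to 0.0566 without WT 1). Mog lost its call without both WT 3 and cKO 1 (limma adjusted p = 0.0698).

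Several lists mark cells outside the Emx1 lineage. Of 28 GABAergic interneuron markers, 9 fell, none rose and 19 did not pass, and 11 were lower adjusted over the list alone. The homeobox gene Dlx2 fell from 11.5 ± 0.645 to 8.2 ± 1.02 FPKM (limma adjusted p = 0.00965), the chemokine receptor Ackr3 from 6.20 ± 0.274 to 4.59 ± 0.371 FPKM and Sp8 from 2.74 ± 0.0262 to 1.8 ± 0.282 FPKM, and Calb2, also a Cajal-Retzius marker, fell. The list was lower, with a median log2 change of −0.19 (camera adjusted p = 7.48e-05; adjusted p = 0.621 with an estimated correlation). Without WT 1, cKO 1 and cKO 2, 3, 3 and 5 members were called lower. Ackr3 lost its call without cKO 1 (adjusted p = 0.0537) and Sp8 without 2 libraries (up to 0.0533 without cKO 1).

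Of 18 microglia and macrophage markers, 7 fell, 1 rose and 10 did not pass, and 11 were lower and 1 higher adjusted over the list alone. The lysosomal protease Ctss fell from 3.84 ± 0.177 to 2.51 ± 0.0896 FPKM, Laptm5 from 1.96 ± 0.0950 to 1.225 ± 0.143 FPKM and Cd68 from 2.57 ± 0.143 to 1.6 ± 0.307 FPKM. The gene that rose was Sall1 (4.48 ± 0.485 to 6.61 ± 0.635 FPKM), which is also expressed in neural progenitors. The list was lower, with a median log2 change of −0.33 (camera adjusted p = 0.000469; adjusted p = 0.808 with an estimated correlation). Without WT 1, 2 members were called lower, and 4 without WT 3, cKO 1 or cKO 2, and Cd68 lost its call without 2 libraries (up to 0.0588 without cKO 2).

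Vascular and meningeal markers held no called gene. None of 21 endothelial, 12 mural and 11 meningeal and fibroblast markers passed limma's test, nor did any adjusted over the list alone (camera adjusted p = 0.425, 0.378 and 0.698). The endothelial genes Igfbp7 and Itm2a were at 12.4 ± 0.428 and 18.0 ± 0.197 FPKM in WT and 10.5 ± 0.739 and 15.1 ± 2.03 FPKM in cKO. Itm2a was called lower without cKO 3 (adjusted p = 0.0160), and 2 endothelial markers were called higher without WT 2. The pericyte genes Rgs5 (23.5 ± 1.76 and 20.6 ± 0.639 FPKM) and Ndufa4l2 (1.91 ± 0.289 and 1.47 ± 0.353 FPKM), and the fibroblast-list genes Lgals1 (4.17 ± 0.570 and 3.27 ± 0.744 FPKM) and Cxcl12 (3.57 ± 0.496 and 4.01 ± 0.0287 FPKM), did not pass.

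Of 6 choroid plexus and ependymal markers, 1 fell (Sostdc1, 1.05 ± 0.213 to 0.533 ± 0.234 FPKM) and 5 did not pass (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.544), and Sostdc1 lost its call without 4 libraries (up to 0.127 without cKO 2). Of 8 erythroid genes, 3 fell and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00233; adjusted p = 0.725 with an estimated correlation). Among them were Car2 (2.76 ± 0.168 to 1.57 ± 0.111 FPKM), a carbonic anhydrase also made by glia, and the globin gene Hbb-bs (40.9 ± 0.154 to 32.7 ± 3.71 FPKM). Hbb-bs has near-identical copies and lost its call without 3 libraries (up to 0.0822 without cKO 1).

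Markers of neighbouring regions changed in both directions. Of 17 striatal and ventral forebrain markers, 3 rose (Meis2 and Gng7 among them), 2 fell (Ppp1r1b, Foxp1) and 12 did not pass, and 3 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.568). The homeobox gene Meis2 rose from 20.3 ± 0.435 to 33.6 ± 0.255 FPKM (limma adjusted p = 5.95e-05). Without cKO 1 no member was called lower, without WT 1 or cKO 2 only 1 was, and without WT 2 5 were higher. Ppp1r1b shares 15.7% of its exon length with a gene on the opposite strand. Ppp1r1b and Gng7 lost their calls without cKO 1 (0.0507 and 0.0523) and Foxp1 without 3 libraries (up to 0.116 without cKO 2). Of 16 hippocampal markers, 6 fell, 2 rose (Meis2, Cpne4) and 8 did not pass, and 6 were lower and 3 higher adjusted over the list alone (camera adjusted p = 0.378). The neuropeptide gene Grp fell from 10.3 ± 3.10 to 3.54 ± 0.285 FPKM, Man1a from 2.61 ± 0.269 to 1.19 ± 0.154 FPKM and Mef2c from 86.7 ± 2.68 to 65.0 ± 1.5 FPKM.

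Cell adhesion genes, the subject of the series title, changed in both directions in most families. Of 42 immunoglobulin-superfamily adhesion molecules, 13 fell, 5 rose (Negr1, Kirrel, Ncam2, Mdga2, Dscaml1) and 24 did not pass, and 15 were lower and 7 higher adjusted over the list alone. Besides Cntn2 and Mdga1, genes that fell included Cadm2 (33.0 ± 0.516 to 16.1 ± 0.383 FPKM, limma adjusted p = 6.26e-06) and Opcml (25.6 ± 1.41 to 14.1 ± 0.1 FPKM, limma adjusted p = 4.45e-05). Kirrel rose from 2.38 ± 0.281 to 4.69 ± 0.594 FPKM and Negr1 from 10.8 ± 0.597 to 17.0 ± 1.40 FPKM. As a list they were lower, with a median log2 change of −0.15 (camera adjusted p = 0.00109; adjusted p = 0.808 with an estimated correlation). Dscaml1 lost its call without 2 libraries (up to 0.0718 without cKO 1).

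Of 30 classical and atypical cadherins, 9 rose, 8 fell and 13 did not pass, and 10 were higher and 8 lower adjusted over the list alone (camera adjusted p = 0.857). The calsyntenin gene Clstn2 fell from 41.7 ± 2.07 to 19.0 ± 1.79 FPKM (limma adjusted p = 2.12e-05), Cdh22 from 1.07 ± 0.186 to 0.267 ± 0.0611 FPKM, Cdh12 from 6.34 ± 0.471 to 3.55 ± 0.215 FPKM and Cdh20 from 5.33 ± 0.190 to 3.22 ± 0.133 FPKM. Without WT 1, cKO 1 or cKO 2, 5 cadherins were called higher, and without WT 1 5 were called lower. Of 12 delta-protocadherins, 4 rose (Pcdh17, Pcdh10, Pcdh18, Pcdh11x), 3 fell (Pcdh9, Pcdh7, Pcdh20) and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.881). Pcdh9 fell from 21.6 ± 1.28 to 10.7 ± 1.05 FPKM and Pcdh7, which shares 21.1% of its exon length with a gene on the opposite strand, from 11.3 ± 0.577 to 7.47 ± 0.416 FPKM. Pcdh17 rose from 10.4 ± 1.05 to 15.4 ± 0.115 FPKM and Pcdh10 from 7.75 ± 0.806 to 11.4 ± 0.263 FPKM. Pcdh20 lost its call without 4 libraries (up to 0.0721 without cKO 2). None of 54 clustered protocadherins passed limma's test, nor adjusted over the list alone (camera adjusted p = 0.769). Pcdhb6 was at 1.56 ± 0.183 FPKM in WT and 1.09 ± 0.405 FPKM in cKO (called lower without cKO 2, adjusted p = 0.0237), and Pcdhgb8, which shares exons with the other gamma genes, at 1.36 ± 0.104 and 0.991 ± 0.295 FPKM.

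Of 39 neurexins and synaptic organisers, 8 fell, 3 rose (Slitrk3, Flrt2, Lrrtm1) and 28 did not pass, and 10 were lower and 7 higher adjusted over the list alone (camera adjusted p = 0.378). Cbln4 fell from 3.75 ± 0.958 to 0.335 ± 0.0464 FPKM, its paralog Cbln1 from 8.80 ± 0.0686 to 3.44 ± 0.555 FPKM and Flrt3 from 17.4 ± 3.08 to 9.89 ± 0.717 FPKM, and Slitrk3 rose from 8.30 ± 0.897 to 12.8 ± 0.547 FPKM. Without cKO 2, 5 members were called lower, and with the length and GC correction 13 were lower and 5 higher. Without both WT 3 and cKO 1 the list was lower (camera adjusted p = 0.0191). Flrt2 and Lrrtm1 lost their calls without 2 and 3 libraries (up to 0.0710 without cKO 2 and 0.0965 without cKO 3). Of 45 integrin and matrix genes, 9 fell, 5 rose (Itgb8, Col11a1, Vcan, Itga4, Thbs2) and 31 did not pass, and 10 were lower and 6 higher adjusted over the list alone. Fibronectin, Fn1, fell from 14.5 ± 1.98 to 3.69 ± 0.160 FPKM (limma adjusted p = 5.24e-06), the proteoglycan Bcan from 23.4 ± 2.16 to 13.8 ± 1.17 FPKM and the laminin chain Lamb1 from 5.36 ± 0.0743 to 3.47 ± 0.285 FPKM, and the integrin Itgb8 rose from 6.69 ± 0.393 to 10 ± 0.775 FPKM. The list did not pass (camera adjusted p = 0.0778), but was lower without WT 3 (0.00986) and with the length and GC correction (0.00726). Without cKO 1, 4 members were called lower, and 5 without WT 1, WT 2, cKO 2 or cKO 3. Itga4 and Thbs2 lost their calls without 4 and 5 libraries (up to 0.0960 without cKO 2 and 0.101 without WT 1), and 3 members were called higher without WT 1, WT 3 or cKO 2.

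Guidance genes also changed both ways. Robo1, a receptor for Slit ligands, rose from 35.9 ± 2.10 to 69.9 ± 2.84 FPKM (limma adjusted p = 1.78e-05), and Robo3 fell from 0.884 ± 0.131 to 0.119 ± 0.0572 FPKM (limma adjusted p = 0.000181). Of 21 Slit, Robo and netrin genes, 5 rose (Robo1, Robo2, Srgap1, Rgma, Unc5c), 3 fell (Robo3, Ntn1, Ntn4) and 13 did not pass, and 8 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.622). Without WT 1 or cKO 2, 3 members were called higher, 8 without WT 2, and 5 were lower without WT 3. Robo2, Rgma, Unc5c and Ntn4 lost their calls without 2, 1, 3 and 5 libraries (up to 0.141 for Ntn4 without cKO 1). Of 30 semaphorin, plexin and neuropilin genes, 7 fell, 3 rose (Sema3c, Sema3f, Sema3a) and 20 did not pass, and 9 were lower and 6 higher adjusted over the list alone (camera adjusted p = 0.425). Sema7a fell from 43.5 ± 0.542 to 19.0 ± 0.583 FPKM (limma adjusted p = 2.91e-06), Sema4d from 7.07 ± 0.825 to 4.03 ± 0.383 FPKM, and Sema3c rose from 17.3 ± 1.69 to 27.5 ± 2.38 FPKM. Sema3a lost its call without 2 libraries (up to 0.0812 without WT 1), and 5 members were called higher without WT 2.

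Of 21 Eph receptors and ephrins, 4 fell (Ephb6, Epha6, Efna5, Epha7), 3 rose (Epha10, Efnb1, Efna3) and 14 did not pass, and 5 were lower and 4 higher adjusted over the list alone (camera adjusted p = 0.638). Ephb6 fell from 23.9 ± 1.82 to 14.6 ± 0.818 FPKM and Epha6 from 2.99 ± 0.789 to 1.14 ± 0.197 FPKM, and Epha10 rose from 0.548 ± 0.0622 to 1.07 ± 0.128 FPKM. Efnb1, Efna3 and Epha7 lost their calls without 4, 5 and 2 libraries (up to 0.139 for Efna3 without WT 1), and without WT 1, WT 3, cKO 1 or cKO 2 1 member was called higher. Of 30 genes of the Reelin pathway and neuronal migration, 3 fell and 27 did not pass, and 2 were lower adjusted over the list alone (camera adjusted p = 0.71). They were Cdk5r2, an activator of the kinase Cdk5 (27.5 ± 2.15 to 9.79 ± 1.216 FPKM, limma adjusted p = 1.15e-05), Rnd3 (13.8 ± 1.05 to 8.87 ± 0.969 FPKM) and Cxcr4 (19.0 ± 1.26 to 15.1 ± 2.02 FPKM), which lost its call without 5 libraries (up to 0.161 without WT 1).

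Of 37 Wnt pathway genes, 10 fell, 1 rose (Lgr6) and 26 did not pass, with the same counts adjusted over the list alone. After Dkk3, the ligand Wnt7b fell from 26.5 ± 3.09 to 9.12 ± 0.127 FPKM (limma adjusted p = 6.26e-06), Apcdd1 from 19.3 ± 2.64 to 11.6 ± 0.647 FPKM and Rspo2 from 7.82 ± 0.807 to 5.27 ± 0.488 FPKM. It did not pass as a list (camera adjusted p = 0.0556), but was lower without WT 3 (0.0228), without cKO 2 (0.0198) and with the length and GC correction (0.0275). Without WT 1, 5 members were called lower, and 6 without cKO 1 or cKO 3, and Lgr6 lost its call without 4 libraries (up to 0.0838 without cKO 3). Of 32 BMP and TGF-beta pathway genes, 9 fell, 4 rose (Bmp3, Nog, Bmpr1b, Smad1) and 19 did not pass, and 11 were lower and 6 higher adjusted over the list alone. Fst, Id2 and Id3 led the list, and the receptor Acvr1 fell from 13.8 ± 1.254 to 8.41 ± 0.504 FPKM. As a whole it did not pass (camera adjusted p = 0.0556), but was lower without WT 3 (0.0389), cKO 2 (0.0353) or cKO 3 (0.0498) and with the length and GC correction (0.0275). Without cKO 1, 5 members were called lower and 1 higher, and Nog, Bmpr1b and Smad1 lost their calls without 3, 4 and 5 libraries (up to 0.167 for Smad1 without WT 1). Of 24 Notch pathway genes, 2 rose (Maml2, 4.09 ± 0.157 to 5.87 ± 0.305 FPKM, and Mfng), 1 fell (Dner) and 21 did not pass, with 2 higher and none lower adjusted over the list alone (camera adjusted p = 0.378), and Dner lost its call without 5 libraries (up to 0.169 without cKO 2).

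Of 31 presynaptic vesicle genes, 8 fell, 3 rose (Syt2, Syn3, Syt7) and 20 did not pass, with the same counts adjusted over the list alone. Syt4 fell from 165 ± 11 to 66.0 ± 4.41 FPKM (limma adjusted p = 5.24e-06), Cplx2 from 92.1 ± 2.5 to 58.8 ± 1.55 FPKM and the SNARE gene Snap25 from 40.3 ± 0.182 to 29.0 ± 1.14 FPKM. The group as a list did not pass (camera adjusted p = 0.0783), but was lower without WT 3 (0.00278), without cKO 1 (0.0294) and with the length and GC correction (0.0275). Syn3 and Syt7 lost their calls without 1 and 2 libraries (0.0569 without cKO 1, up to 0.0515 without WT 1), and without cKO 1 1 member was called higher. Of 29 glutamate receptor genes, 7 fell, 3 rose (Gria2, Grik2, Gria4) and 19 did not pass, and 11 were lower and 3 higher adjusted over the list alone. Grm2 fell from 7.26 ± 0.671 to 4.30 ± 0.379 FPKM, Cnih3 from 13.5 ± 0.510 to 9.36 ± 0.626 FPKM, Grin3a from 8.18 ± 1.76 to 4.21 ± 0.527 FPKM and Grm4 from 1.11 ± 0.0269 to 0.6 ± 0.0250 FPKM. These genes did not pass as a list (camera adjusted p = 0.0783), but was lower without WT 3 (0.00415), without cKO 1 (0.0367) and with the length and GC correction (0.0253). The 3 genes that rose lost their calls without 3, 5 and 6 libraries (up to 0.132 for Grik2 without cKO 2).

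Of 19 GABA and glycine receptor genes, 6 fell, 2 rose (Glra2, Glra3) and 11 did not pass, and 8 were lower and 4 higher adjusted over the list alone (camera adjusted p = 0.378). Glra3 rose 9.08-fold from 0.0473 ± 0.0168 to 0.430 ± 0.0563 FPKM, while Gabra5 fell from 20.5 ± 1.36 to 12.4 ± 0.973 FPKM. Without WT 1, cKO 1 or cKO 3, 3 members were called lower. Of 44 voltage-gated sodium and potassium channel genes, 11 fell, 4 rose (Kcnq5, Scn2b, Kcnc2, Kcnc4) and 29 did not pass, and 11 were lower and 8 higher adjusted over the list alone (camera adjusted p = 0.425). Kcna1 fell from 1.86 ± 0.111 to 0.250 ± 0.0229 FPKM (limma adjusted p = 6.92e-06) and the inward rectifier Kcnj2 from 7.53 ± 0.679 to 1.88 ± 0.310 FPKM, and Kcnq5 rose from 6.55 ± 0.673 to 12.2 ± 1.37 FPKM. Without WT 1 and cKO 2, 6 and 7 members were called lower, 2 were higher without WT 1, cKO 1 or cKO 3, and Kcnc2 and Kcnc4 lost their calls without 3 and 4 libraries (up to 0.0943 for Kcnc4 without WT 1). Of 19 calcium channel genes, 1 rose (Cacna2d2, 5.46 ± 0.384 to 7.18 ± 0.655 FPKM, lost without 4 libraries, up to 0.0970 without cKO 1) and 18 did not pass, also adjusted over the list alone (camera adjusted p = 0.857).

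Of 26 neuropeptides and their receptors, 11 fell, 6 rose and 9 did not pass, and 12 were lower and 8 higher adjusted over the list alone. Besides Nts, the granin-like Vgf fell from 10.3 ± 0.427 to 1.98 ± 0.238 FPKM and cholecystokinin, Cck, from 37.5 ± 3.67 to 15.1 ± 0.125 FPKM, and the somatostatin receptor Sstr1 rose from 9.32 ± 1.09 to 19.8 ± 1.70 FPKM. Camera did not call the list (camera adjusted p = 0.0745), but was lower without WT 3 (0.0401), and 3 members were called higher without WT 1. Of 17 immediate early genes, which respond to neuronal activity, 9 fell, 1 rose (Jun) and 7 did not pass, and 10 were lower and 2 higher adjusted over the list alone. Nr4a3 fell from 29.6 ± 3.48 to 9.37 ± 2.22 FPKM (limma adjusted p = 0.000131), Nr4a2 from 33.4 ± 6.61 to 15.2 ± 2.15 FPKM, Nptx2 from 4.15 ± 0.719 to 2.10 ± 0.258 FPKM and Arc from 0.591 ± 0.154 to 0.152 ± 0.0215 FPKM. As a list they were lower, with a median log2 change of −0.27 (camera adjusted p = 0.00253; adjusted p = 0.621 with an estimated correlation).

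Mitochondrially encoded genes were lower in cKO. Of 13 measured, 10 fell and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 4.57e-06; adjusted p = 0.808 with an estimated correlation). The oxidase subunit mt-Co2 fell from 72.5 ± 10.8 to 42.7 ± 3.16 FPKM (limma adjusted p = 0.00125) and mt-Co3 from 72.1 ± 8.92 to 44.0 ± 4.03 FPKM, and the ATP synthase genes mt-Atp6 and mt-Atp8, which overlap, also fell. The share of reads of all measured genes on the mitochondrial chromosome, not of the 13 listed genes alone, was 1.88%, 1.83% and 2.16% in WT and 1.42%, 1.77% and 1.70% in cKO (exact permutation test, 2-sided, n = 3 per group, p = 0.1, the smallest this design allows). Of 30 nuclear genes of oxidative phosphorylation, 6 fell and 24 did not pass, and 15 were lower adjusted over the list alone (camera adjusted p = 2.49e-06; adjusted p = 0.808 with an estimated correlation). Ndufa1 fell from 63.9 ± 5.53 to 50.1 ± 4.91 FPKM, Ndufb3 from 50.3 ± 5.19 to 40.3 ± 2.60 FPKM, Ndufa5 from 28.7 ± 2.99 to 22.4 ± 2.52 FPKM and Ndufb9 from 113 ± 10.2 to 92.5 ± 8.16 FPKM. These 4 calls were lost without 3 to 5 libraries (up to 0.149 for Ndufb9 without cKO 1) and with the length and GC correction (adjusted p of 0.0768 for Ndufa5 to 0.136 for Ndufb9). Ndufb9 shares 19.5% of its exon length with another gene, and without WT 1 2 members were called lower and without WT 3, cKO 1 or cKO 2 none.

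Of 40 ribosomal protein genes, 1 fell (Rps2, 290 ± 19.4 to 249 ± 5.85 FPKM) and 39 did not pass, with none called adjusted over the list alone. As a list they were lower, with a median log2 change of −0.20 (camera adjusted p = 1.47e-06; adjusted p = 0.817 with an estimated correlation). Rps2 has pseudogene copies and lost its call without each of the 6 libraries (up to 0.151 without cKO 2). Ribosomal and mitochondrial transcripts are short, and the deviation of a library from the mean correlated with exon length across genes at −0.0773, 0.00514 and −0.337 in WT and 0.198, 0.212 and 0.0957 in cKO (Spearman rho, exact permutation test between groups, n = 3 each, p = 0.1, the smallest possible). With the correction for length and GC content the median of the ribosomal list was −0.12, and those of the mitochondrial and the nuclear oxidative phosphorylation lists were −0.36 and −0.14.

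Of 23 glycolysis and hypoxia genes, 3 rose, 1 fell and 19 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.177). Adm rose from 0.402 ± 0.121 to 1.35 ± 0.406 FPKM, Egln3 from 4.60 ± 0.307 to 7.09 ± 0.599 FPKM and Mxi1 from 7.43 ± 1.81 to 10.6 ± 0.452 FPKM (lost without 5 libraries, up to 0.105 without cKO 2), and Ndrg1 fell from 15.2 ± 0.504 to 10.6 ± 0.700 FPKM. Without WT 2, 8 members were called higher and the list was higher (adjusted p = 0.0120). Of 19 p53 targets and apoptosis genes, 1 rose (Trp53inp1), 4 fell (Plk2, Pmaip1, Phlda3, Perp) and 14 did not pass, and 2 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.378). Trp53inp1 rose from 9.37 ± 1.42 to 14.7 ± 1.82 FPKM and Plk2 fell from 100.1 ± 4.07 to 74.5 ± 1.95 FPKM, and Perp lost its call without 4 libraries (up to 0.0977 without WT 1). Without WT 2, 3 p53 targets were called higher.

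Of 13 interferon response genes, 2 fell (H2-D1, Ifitm3), 1 rose (Irf9) and 10 did not pass, and 3 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.378). Ifitm3 fell from 4.64 ± 1.2 to 2.57 ± 0.443 FPKM. With 1 library left out in turn, 0 to 5 interferon response genes were called lower and 0 to 2 higher. The 3 calls were lost without 2, 4 and 4 libraries (up to 0.0760 without WT 1, 0.0888 without cKO 1 and 0.15 without WT 1). Of 20 cholesterol biosynthesis genes, 1 rose (Sc5d, 16.1 ± 1.99 to 20.3 ± 0.514 FPKM), 1 fell (Mvk, 10.7 ± 0.261 to 9.06 ± 0.0892 FPKM) and 18 did not pass, with none called adjusted over the list alone (camera adjusted p = 0.614). Sc5d and Mvk each lost their calls without 5 libraries (up to 0.1 without cKO 1 and 0.15 without cKO 2), and without WT 2 5 members were called higher and the list was higher (adjusted p = 0.0379).

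**Figure D3:**
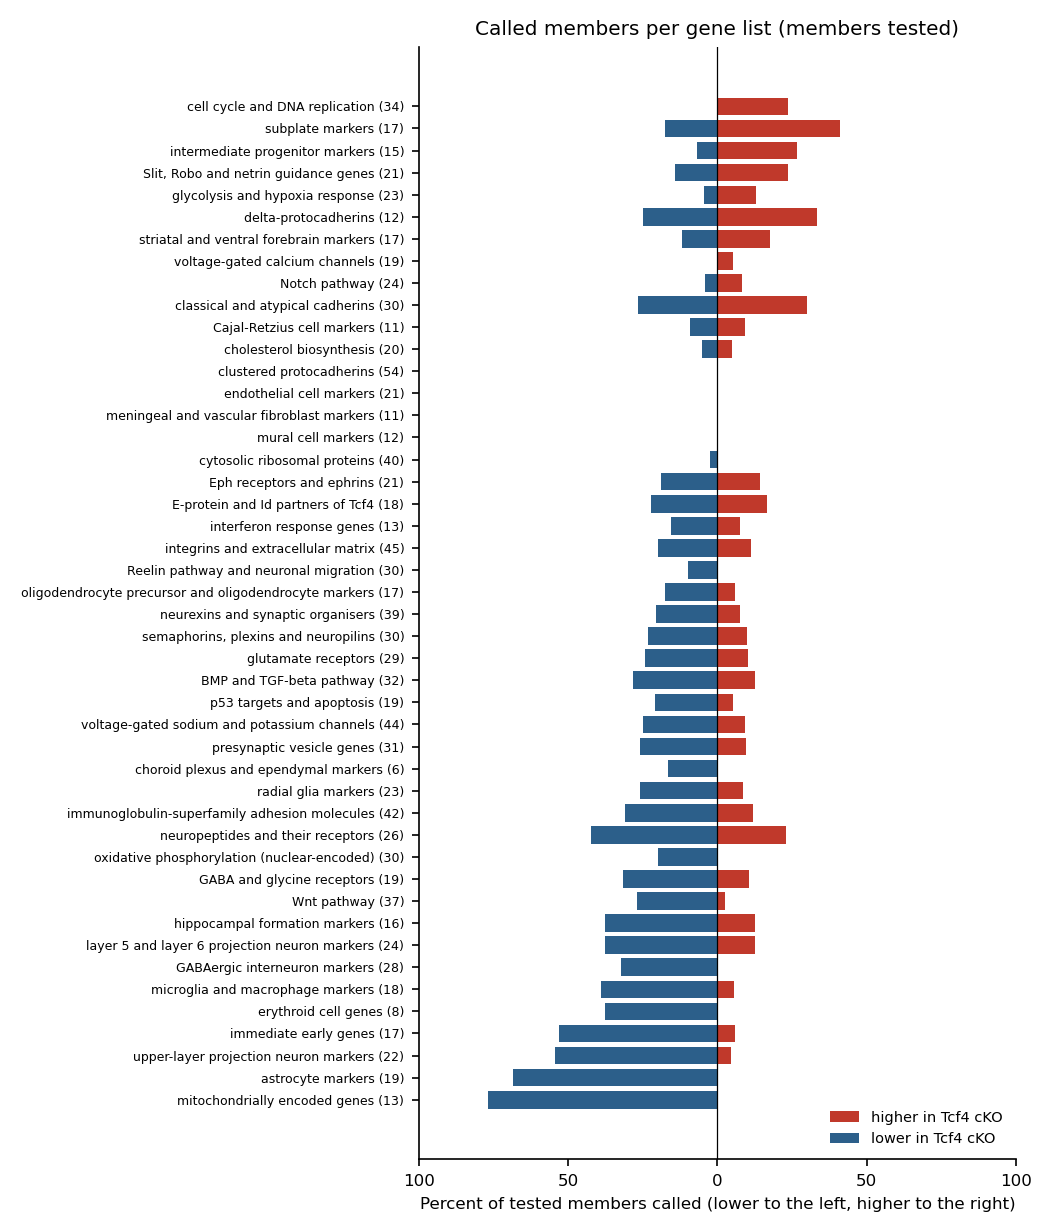
Percent of the measured members of each of the 46 gene lists called higher (red, to the right) or lower (blue, to the left) in Tcf4 cKO, with the number measured in brackets. Astrocyte and mitochondrially encoded genes reach furthest to the left, with 13 of 19 and 10 of 13 called lower, and clustered protocadherins, endothelial, mural and meningeal markers show no bar.

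In all, 13 of the 46 lists were shifted by camera at the preset correlation, 2 higher and 11 lower, and none with an estimated correlation. The median, mean and test of a list differed in sign for 6 lists. Cadherins had a median log2 change of 0.03 and a mean of −0.04 with camera up and fry down, and delta-protocadherins had positive values with fry down. Semaphorins and Reelin pathway genes had medians of 0.0019 and 0.0043 and means of −0.09 and −0.06 with both tests down. Slit and Robo genes and calcium channels had medians of −0.03 and means of 0.04 and 0.0088 with both tests up.

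The sex-linked genes showed both sexes in both groups. Ddx3y was at 16.1 FPKM in WT 1 and 14.7 FPKM in cKO 3 and at most 0.0250 FPKM in the other 4 libraries, while Xist was at 0.433 and 0.407 FPKM in WT 1 and cKO 3 and at 127 to 158 FPKM in the others. Kdm5d, Uty and Eif2s3y followed Ddx3y. No gene had a sex by genotype interaction in limma (405 at an unadjusted p under 0.05), with a single male per group. Limma's p-values for genes describe the spread between 3 animals per group. Camera at the preset correlation compares the genes of a list with other genes. The Fisher and gene permutation tests used further on take genes as units. Those p-values therefore do not measure the spread between animals. Bulk tissue does not separate a change within cells from a change in their number.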

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

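The counts of 1134 genes higher and 1349 lower and of 13 shifted lists were recomputed under each alternative. Leaving out 1 library gave 544 (without WT 1) to 1572 (without WT 2) genes higher, 830 (without WT 1, and equally without cKO 1) to 1517 (without WT 2) lower, and 13 (without WT 1 or WT 2) to 20 (without WT 3, stronger) shifted lists. Without cKO 1, cKO 2, cKO 3 and WT 3, 566, 578, 840 and 801 genes were higher, and 830, 839, 1066 and 1130 lower, with 16, 16, 14 and 20 lists. The counts without WT 1, cKO 1 and cKO 2 were weaker. An adjusted p under 0.01 gave 371 higher and 624 lower (weaker), which follows from the stricter threshold. Pseudocounts of 0.1 and 5 gave 1137 and 1114 higher and 1342 and 1313 lower with 13 lists each, a mean of at least 1 CPM 1163 and 1307 with 13, sex as a covariate 932 and 1156 with 13, and limma voom on recovered reads 1515 and 1440 with 17. The replicate number as a block gave 1274 and 1541 with 12 lists, the subplate list (adjusted p = 0.0702) and the genes Aldoc, Nrgn, Cxcr4, Irf9, Efna3, Smad1 and Mvk not passing in that fit. The deviations of libraries that share a number from their group means correlated at −0.0462, 0.0998 and −0.0476, and the highest value was 0.206 for WT 1 with cKO 3. These values gave no sign of pairing by number, but deviations from means of 3 libraries cannot exclude it. Camera with a correlation estimated per list shifted 0 lists (weaker), where 13 had passed at the preset correlation. Fry shifted 11, of which 8 were shared with those 13. It added the Wnt (fry adjusted p = 0.0227), BMP and TGF-beta (0.00316) and neuropeptide (0.00316) lists, all lower. Not called by fry were the microglia (0.0984), cell cycle (0.163), mitochondrially encoded (0.0785), nuclear oxidative phosphorylation (0.118) and ribosomal (0.204) lists. Among alternatives chosen after the data had been seen, median-of-ratios scaling gave 1136 and 1349 with 13 lists, upper-quartile scaling 1091 and 1405 with 13, a mean FPKM of at least 1 gave 1048 and 1165 with 18, the length and GC correction 1292 and 1331 with 17, and that correction with the block 1264 and 1319 with 17. Leaving out both libraries at the ends of the length trend gave 482 and 823 (weaker) with 18 lists, and a change of more than 1.2-fold by limma treat 122 and 258 (weaker), which follows from the threshold. For the counts that moved with left-out libraries and for the lists under an estimated correlation the cause was not tested. The estimated correlation was 0.927 for ribosomal proteins but −0.0121 for upper-layer markers, below the preset 0.01. Correlation among its members therefore cannot account for the loss of the upper-layer list. Across the named genes, no alternative turned the direction of a called gene. Counted over each gene in each alternative, the call was unchanged in 4042 cases, lost in 363 and gained in 8. Bcl11b (−0.10 to 0.11 log2 with 1 library left out) and the sex-linked Xist, Ddx3y, Kdm5d, Uty and Eif2s3y, none of them called, changed sign. With the length and GC correction Ndufa1, Ndufb3, Ndufa5, Ndufb9, Hbb-bs, Cxcr4, Rps2, Mvk, Etv1, Nrgn, Itga4, Thbs2, Sema3a, Unc5c, Grik2 and Perp did not pass. Further calls were lost with sex as a covariate and without both libraries at the ends of the length trend. In the latter fit Mog, Laptm5 and Ntn1, whose calls held without each single library, did not pass. Tcf12 passed with voom (adjusted p = 0.0450). The planned count models, their size factors and surrogate variables were not run because the table holds FPKM and whole reads were checked for low, short genes only, and having no filter is the same as the fit used. With 3 animals per group and about 25.4 to 28.7 M recovered reads (M, 1e6), 70% of simulated 1.5-fold changes were recovered. Only 200 genes were changed there, so this share may be too low for the real data. A gene that did not pass may still have changed by 1.5-fold.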

Other observations

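All tests in this section were chosen after results had been seen, except that the explanations for the zinc finger genes, neuronal maturity and adjacent genes were written down before their tests were run.

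Families were defined by symbol alone, 162 in all. Of 10 genes with the Camk stem, which holds calcium signalling kinases and related genes, 5 were called lower, 0 higher and 5 did not pass (1-sided Fisher's exact test, Benjamini-Hochberg adjusted over the families, p = 0.0275). Camk1d fell from 11.7 ± 1.201 to 3.78 ± 0.18 FPKM (limma adjusted p = 6.74e-06), Camk4 from 12.97 ± 1.195 to 8.25 ± 0.411 FPKM and Camk2a, the main kinase of mature excitatory synapses, from 8.46 ± 1.229 to 5.12 ± 0.559 FPKM. Camk2b lost its call without 4 libraries (up to 0.136 without cKO 2) and Camk2g without 2. The phosphatase Ppp3ca, the catalytic subunit of calcineurin, fell from 43.3 ± 0.208 to 30.3 ± 0.670 FPKM. Of 20 genes with the Dusp stem, which holds phosphatases of MAP kinases and other phosphatases, 7 fell (adjusted p = 0.0275) and 2 rose (Dusp18, Dusp11). Dusp6 fell from 15.5 ± 1.75 to 6.85 ± 0.725 FPKM and Dusp5 from 2.01 ± 0.635 to 0.148 ± 0.0102 FPKM, with 22.1% of its exon length shared with a gene on the opposite strand. Of 31 Klhl genes, which encode adaptors of ubiquitin ligases, 9 rose (7 after the length and GC correction, adjusted p = 0.0230 before it) and 2 fell, Klhl25 rising from 13.1 ± 1.772 to 23.4 ± 0.924 FPKM. Of 17 genes with the Cdh stem, 7 rose (adjusted p = 0.0149), Cdh18 from 1.87 ± 0.194 to 3.81 ± 0.451 FPKM, and 6 fell (adjusted p = 0.0562).

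Among biotypes, 220 of 535 processed pseudogenes were called lower and 7 higher, with a median log2 change of −0.33 that was −0.18 with the length and GC correction. Their median exon length was 627 bases. The pseudogene Gm8210 was at 25.2, 26.1 and 21.9 FPKM in WT and 0.350, 25.6 and 0.715 FPKM in cKO, so cKO 2 stood with WT (limma adjusted p = 0.263). Within 10 Mb of Tcf4, 21 of 109 genes were called (19.3%, Fisher's exact test, p = 0.355), and within 10 Mb of Emx1, 25 of 149 (16.8%, Fisher's exact test, p = 0.735).

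Neither camera with an estimated correlation (camera adjusted p = 0.808) nor fry (fry adjusted p = 0.0785) called the mitochondrially encoded list. At the preset correlation these genes were lower as a list, with 10 of 13 called. The length trend of the libraries might account for this, but 10 of 10 calls remained after the length and GC correction, with the median moving from −0.46 to −0.36. A larger nuclear share of the RNA could also lower them, and 11 nuclear-retained RNAs had a median log2 change of 0.148 (bootstrap interval −0.0411 to 0.218) with 0 called, which leaves this undecided.

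Markers of interneurons and microglia, cells outside the Emx1 lineage, were lower as lists at the preset correlation, with 9 of 28 and 7 of 18 called (3 and 2 without WT 1), but not with an estimated correlation (camera adjusted p = 0.621 and 0.808). Fewer cells of every such type could give this, but the vascular and meningeal median exceeded that of 28 interneuron markers by 0.145 (permutation of genes, p = 0.00067) and that of 18 microglia markers by 0.278 (permutation, p = 1e-05, the smallest possible), with 0 of 44 vascular genes called. Genes within a list are not independent, so these p-values are too small. Fry called the interneuron list lower (fry adjusted p = 0.0227) and did not call the microglia list (0.0984). The length trend was weighed by its correction, after which the medians were −0.211 (interval −0.258 to −0.143, 7 of 9 calls kept) and −0.272 (−0.370 to −0.169, 4 of 7 kept), while 3 and 1 markers were called lower without both libraries at the ends of the trend.

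More Zfp zinc finger genes were called higher than other coding genes, 45 of 350 against 6.94%, with 3 lower and the rest not passing (1-sided Fisher's exact test, adjusted p = 0.0149). The length trend might do this, but 39 of 45 calls remained after the correction. Shared reads between neighbouring paralogs could do so too, but 12.7% of 150 Zfp genes with none other within 100 kb were called higher, against 6.94% of other coding genes (1-sided Fisher's exact test, p = 0.00863).

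A less mature state of the neurons is a hypothesis for the rise of Eomes and Neurog2 and the fall of Syt4 and Snap25. The intermediate progenitor and presynaptic lists did not pass (camera adjusted p = 0.378 and 0.0783). Genes that rise late had a median lower by 0.112 than early ones (permutation of genes, p = 0.0797), which does not decide it. Local co-regulation was a further hypothesis, weighed on adjacent called genes within 100 kb, overlapping genes and shared symbol stems left out. They shared a direction in 73.5% of 223 pairs against 50.4% in permuted order (permutation, p = 0.0001, the smallest possible). After the length and GC correction the share was 76.6% of 239 pairs. Before it, the share was 75.5% of 110 opposite-strand and 71.7% of 113 same-strand pairs. Whether reads shared between neighbours contributed was not tested.

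Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as genotype (2483, highest other 0). Every other split mixed WT and cKO libraries in both groups. Genotype differences then add to the spread within groups, so 0 calls there say little about how many arise by chance. For shifted lists, 4 of 10 splits, genotype included, reached its 13, and the 9 others shifted 5 to 22 lists at the preset correlation. With 10 splits no share under 0.05 is possible. The 3 other splits that reached it put WT 1 and WT 2 against WT 3. A structure of the samples besides genotype could give this. So could a list test that calls too many lists where members are correlated, and no test told these apart.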
